A study of Mus musculus with 7 samples.

How the data were processed

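The data were polyA RNA-seq libraries of RFP-positive sarcoma cells sorted from mouse tumours, 4 labelled as the p53 knockout model with Ccne1 overexpression and 3 labelled as the p53 knockout model with Vgll3 overexpression. RNA was extracted with TRIzol, per the labels' protocols. Groups and replicate numbers were taken from the sample titles.

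The deposited table holds estimated counts per Ensembl gene, 1 column per library, not scaled between libraries. Per the submitters' processing notes, the authors used Salmon and the mouse genome build mm10; the Salmon version, the annotation and the tool that summed transcripts to genes are not given in the sources used here. Whether strand was used in counting is not given either, so overlapping and antisense genes cannot be told apart, and genes with near-identical copies (Magea8, Hba-a1 and Hba-a2, Ifit3 and Ifit3b, H2-K1 and H2-D1) are uncertain because a read estimate can be split among copies. All values in the table were whole, and 0 values needed rounding. The table had 35727 genes, of which 35422 had a symbol and 35493 coordinates in a reference annotation of the same genome build (GRCm38, equal to mm10), and 23095 had a count in any library. Coordinates are 1-based gene bounds from that annotation.

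Library totals ranged from 21725890 to 53610300 counts. A count of 3, taken as the limit that a count of 0 allows, stood for 0.0560 to 0.138 CPM, which covers counting error only. Within each group, pairs of libraries differed far beyond sampling noise (chi-square per degree of freedom 11.7 to 88.9), so no library was a copy of another. On log2 CPM, principal component 1 held 67.3% of the variance and separated the models, and component 2 held 14.4% and separated Vgll3 replicate 3 from the others.

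Genes were tested with edgeR 4.0.16 (R 4.3.3): filterByExpr with default settings, TMM scaling, and the robust quasi-likelihood F test with the model as the only term. P-values were adjusted with Benjamini-Hochberg at a threshold of 0.05. The log2 fold change is Vgll3-labelled over Ccne1-labelled, and its SE is the absolute log2 fold change divided by the square root of F. CPM used TMM effective library sizes. The biological coefficient of variation was 20.7%. Single values were also compared with two-sided exact permutation tests over the 35 splits of 7 libraries into 4 and 3, which cannot give a p under 0.0286.

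Before the data were examined, 5 primary lists (collagens, matricellular proteins, macrophage attractants and growth factors, YAP/TAZ-TEAD targets, G1/S and replication genes), 14 secondary lists and 12 lists of host cell markers and dissociation stress genes were fixed. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 on log2 CPM with a prior count of 3, adjusted over the 19 pathway lists, and separately over the marker and stress lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation, camera takes its degrees of freedom from the 7 libraries instead of the genes, which leaves it little power here. Members were also counted with p-values adjusted over the list alone. Sums of marker CPM were adjusted over the 12 marker and stress lists too. With a smallest permutation p of 0.0286, an adjusted p under 0.05 needs most of these lists at that smallest p.

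The genes named were also fixed by a rule before the data were examined. The rule takes Ccne1, Vgll3, Trp53 and Postn; the 5 genes per direction with the largest log2 fold change among those called, with at least 10 CPM in the higher group and no overlap between groups; the up to 2 most raised and 2 most lowered called members of each primary list, and 1 each of each secondary list; and the member with the highest mean CPM of each marker or stress list and of any list with no called member. This gave 67 genes, of which 66 were tested; Plin1, an adipocyte marker, was too low to test. Other list members given as examples were chosen after their values were seen, among them Csf1, Cxcl12, Vegfa, Col3a1, Sparc, Thbs1, Tgfbi, Ankrd1, Mki67, Ifih1, Rsad2, Tap1, Slc2a1, Bnip3, Itgav, Mmp10, Mmp13, Adamts2, Cdh11, Pdgfra, Pdgfrb, Vim, Sox9, Cebpb, Acta2, Cxcl1, Cxcl10, Rgs5, Notch3, Egr1 and Ier3.

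The gene test was checked on simulated counts with the means and library sizes of these libraries. Of seeded genes, it recovered 30.2% at 1.5-fold, 66.7% at 2-fold and 75.4% at 4-fold among 13531 genes, all with the right sign, and 6.67% of its 120 calls were false. Only 63, 66 and 65 genes were seeded at these folds, while 51.9% of genes were called in the real data. The adjustment is stricter when few genes change, so these rates do not measure the power of the real comparison. In a simulation over 13518 genes, camera called 20 of 20 lists raised 1.4-fold and 0 of 20 unchanged lists. Genes were simulated independently, so this check does not cover lists whose members vary together. In the real libraries the estimated inter-gene correlation was 0.58 for G1/S, 0.76 for interferon-stimulated and 0.86 for G2/M genes. Alternatives were DESeq2 size factors, total library sizes, no low-count filter, at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, glmTreat at 1.5-fold, leaving out each library, and a block on the replicate number. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.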

Results

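The data were RNA-seq estimated counts of mouse sarcoma cells sorted by red fluorescent protein (RFP) from tumours of 2 genetic models of undifferentiated pleomorphic sarcoma, a soft-tissue tumour without a clear line of differentiation. Both models started from mesenchymal stem cells of p53 knockout female mice, transduced with a retroviral vector for Ccne1 (cyclin E1) or Vgll3 (vestigial-like family member 3), passaged as subcutaneous tumours and transplanted again before sorting. There were 4 libraries labelled Ccne1 and 3 labelled Vgll3. Library totals were 21725890, 53610300, 32717269 and 27535228 counts for Ccne1 replicates 1 to 4, and 47504434, 26433220 and 28545527 counts for Vgll3 replicates 1 to 3. Between 17305 and 19022 genes had a count in a library. The labels do not say that each library came from a separate tumour or animal, so the p-values measure the spread between these libraries, which may be partly technical. An effect of the transduced gene also cannot be told apart from other differences between the tumour lines of the 2 models. Values below are mean ± SD in CPM (counts scaled to a common library size), n = 4 Ccne1-labelled and n = 3 Vgll3-labelled libraries, given in that order unless stated otherwise.

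The first comparison asked whether each model's own gene was raised. Vgll3, a cofactor that binds TEAD transcription factors (ENSMUSG00000091243, mm10 chromosome 16, 65815257 to 65866368, protein-coding), was 50.7 ± 8.57 CPM in the Ccne1-labelled and 252 ± 34.6 CPM in the Vgll3-labelled libraries. It was 4.96-fold higher in the latter, with a log2 fold change of 2.31, SE 0.15 and edgeR adjusted p = 1.2e-05. Ccne1, whose protein drives entry into S phase (ENSMUSG00000002068, chromosome 7, 38097984 to 38107534, protein-coding), was not higher in the libraries labelled for it: 12.7 ± 5.61 against 14.9 ± 2.16 CPM, log2 fold change 0.23, SE 0.34, edgeR adjusted p = 0.609. The exact two-sided permutation p over the 35 splits of the libraries was 0.514 for Ccne1 and 0.0286, the smallest these splits allow, for Vgll3. The Ccne1-labelled libraries were uneven, with 6.73, 9.24, 18.3 and 16.7 CPM of Ccne1 in replicates 1 to 4. Vgll3 replicates 1 to 3 had 12.7, 15.1 and 17.0 CPM. The Ccne1 counts lay between 148 and 591 per library. The 95% interval of the fold change left room for a level at most 1.49-fold higher in the Ccne1-labelled libraries. The groups are therefore called by their labels throughout, and every direction below is Vgll3-labelled over Ccne1-labelled. Trp53, the gene of p53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873, protein-coding), was 66.4 ± 2.69 and 70.7 ± 4.32 CPM (edgeR adjusted p = 0.298) in these knockout-derived lines; gene-level counts do not show which part of the transcript the reads cover.

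Postn, which encodes the secreted matrix protein periostin named in the series title (ENSMUSG00000027750, chromosome 3, 54361109 to 54391037, protein-coding), was 22.5-fold higher in the Vgll3-labelled libraries. It was 220 ± 79.5 CPM in the Ccne1-labelled and 4961 ± 1476 CPM in the Vgll3-labelled libraries (log2 fold change 4.49, SE 0.38, edgeR adjusted p = 0.000102). The highest Ccne1-labelled library had 291 CPM and the lowest Vgll3-labelled library, replicate 3, had 3339 CPM (exact permutation p = 0.0286).

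**Figure D1:**
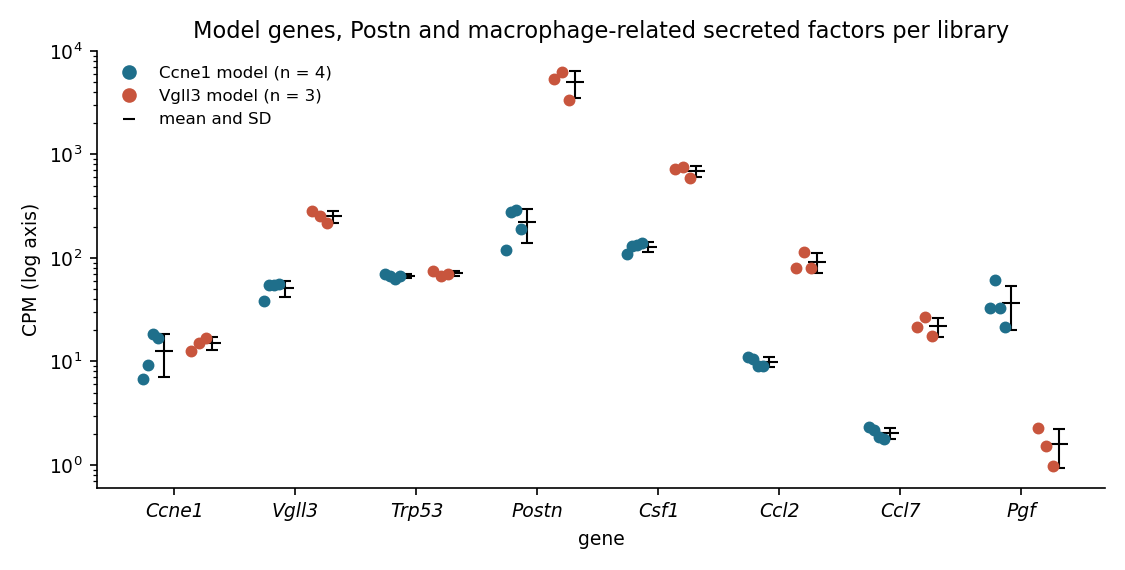
CPM on a log axis for Ccne1, Vgll3, Trp53, Postn and 4 secreted factors (Csf1, Ccl2, Ccl7 and Pgf) in each of the 7 libraries; points are libraries, and bars are the mean and SD per group. The groups overlap for Ccne1 and Trp53 and are apart for the others, with Postn at 220 and 4961 CPM on average.

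Beyond these genes, the models differed widely. Of 13740 genes tested, 7133 (51.9%) passed an edgeR adjusted p of 0.05, with 3454 higher in the Vgll3-labelled and 3679 higher in the Ccne1-labelled libraries. Of these, 2293 differed at least 2-fold, 1264 and 1029 in the same order. The groups did not overlap for 7659 genes (55.7%), where chance gives 5.71%. Without Vgll3 replicate 3, which stood apart from the other libraries of its group (Pearson r across genes 0.959 and 0.963, against 0.980 to 0.988 for all other pairs within a group), 7334 genes were called.

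Among called genes with at least 10 CPM in the higher group and no overlap between groups, the largest rises in the Vgll3-labelled libraries were in Cdh15, Magea8, Rbm20, Dpyd and Itm2a. Cdh15 (chromosome 8), the muscle cadherin of myoblasts and satellite cells, went from 0.112 ± 0.111 to 141 ± 79.0 CPM, a log2 fold change of 10.54 (edgeR adjusted p = 0.000119). Magea8 (chromosome X), a cancer-testis antigen gene, was 0.240 ± 0.1496 and 46.3 ± 14.0 CPM; it belongs to a family of close copies among which reads can be split. Rbm20 (chromosome 19), a splicing factor of titin in muscle, was 0.0754 ± 0.0765 and 12.96 ± 1.37 CPM. Dpyd (chromosome 3), the first enzyme of pyrimidine breakdown, was 0.0990 ± 0.0490 and 11.01 ± 4.64 CPM, and Itm2a (chromosome X) was 0.373 ± 0.352 and 32.5 ± 5.62 CPM. The log2 fold changes of these 4 lay between 6.57 (Itm2a) and 7.65 (Magea8). Leaving out Ccne1 replicate 2 moved that of Cdh15 to 9.87, and leaving out Ccne1 replicate 1 moved those of Itm2a and Rbm20 to 7.18 and 8.08.

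Under the same limits, the largest differences among genes higher in the Ccne1-labelled libraries were in S100g, Osbp2, Disp2, Slitrk6 and Crct1. S100g (chromosome X), which encodes the calcium-binding protein calbindin-D9k, was 10.99 ± 3.16 CPM there and had no count in any Vgll3-labelled library, at least 119-fold lower against a floor of 3 counts per library (0.0927 CPM on average). Osbp2 (chromosome 11), an oxysterol-binding protein, was 33.2 ± 4.93 against 0.233 ± 0.0932 CPM (log2 fold change −7.18, SE 0.23, edgeR adjusted p = 1.02e-06). Disp2 was 32.0 ± 1.93 against 0.322 ± 0.304 CPM, Slitrk6 12.6 ± 3.49 against 0.131 ± 0.176 CPM and Crct1 18.0 ± 8.17 against 0.171 ± 0.0842 CPM. Their log2 fold changes were −6.72, −6.67 and −6.61. Without Vgll3 replicate 3 those of Disp2 and Slitrk6 were −7.82 and −8.66, and that of Slitrk6 was −6.01 without Vgll3 replicate 1 and −7.30 with limma-voom.

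Of the collagen genes on the list, more were higher than lower in the Vgll3-labelled libraries. Of 19 tested, 11 rose and 3 fell (12 and 3 when adjusted over the list alone), with a median log2 fold change of 0.73. Over all 37 tested genes of the Col symbol family, which takes in collagens outside the list and Col4a3bp, not a collagen gene, 16 rose and 5 fell, with a median of 0.33 and a camera adjusted p = 0.1499 over 224 symbol families. The fibrillar collagens led in abundance: Col1a2 was 4197 ± 463 and 17309 ± 2673 CPM (log2 fold change 2.04, edgeR adjusted p = 9.98e-06), and Col3a1 was 4122 ± 665 and 16014 ± 2254 CPM. Col11a1 rose from 86.3 ± 17.6 to 374 ± 123 CPM. The basement membrane chain Col4a1 went the other way, from 2830 ± 122 to 485 ± 418 CPM (log2 fold change −2.54, edgeR adjusted p = 0.0118), and Col14a1 from 16.7 ± 11.5 to 1.47 ± 1.96 CPM (edgeR adjusted p = 0.0465). The list had a camera adjusted p = 0.0146, and adjusted p = 0.596 with an estimated correlation. With the replicate block it was not called (camera adjusted p = 0.0570). The call for Col14a1 ended when Ccne1 replicate 1, 2 or 3 or Vgll3 replicate 2 or 3 was left out (edgeR adjusted p 0.0752 to 0.1202), without a low-count filter (0.112) and with limma-voom (0.135), and its log2 fold change moved from −3.39 to −5.55 without Vgll3 replicate 1. Without Vgll3 replicate 2, 1 collagen fell, and without Vgll3 replicate 3 the log2 fold change of Col4a1 was −3.52.

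Matricellular proteins, the non-structural matrix family that includes periostin, split in both directions. Of 20 tested, 5 were higher in the Vgll3-labelled and 8 in the Ccne1-labelled libraries, the same counts as when adjusted over the list alone. Besides Postn, Ccn5 rose from 2.40 ± 1.24 to 171 ± 71.7 CPM (log2 fold change 6.17, edgeR adjusted p = 0.000117). Sparc, a collagen-binding protein, rose from 1106 ± 133 to 2212 ± 238 CPM. Lower in the Vgll3-labelled libraries were Thbs1 (thrombospondin 1, 2448 ± 303 to 291 ± 48.3 CPM), Tgfbi (1748 ± 168 to 394 ± 89.8 CPM), Smoc2 (2.25 ± 0.866 to 0.218 ± 0.134 CPM) and Tnxb (35.2 ± 23.8 to 2.81 ± 3.06 CPM, edgeR adjusted p = 0.0416). The list as a set was not called (median log2 fold change −0.34, camera adjusted p = 0.594). The call for Tnxb ended without Ccne1 replicate 1, 2 or 3 or Vgll3 replicate 2 or 3 (edgeR adjusted p 0.0692 to 0.110), without a low-count filter (0.0963) and with limma-voom (0.173), and its log2 fold change moved from −3.56 to −4.87 without Vgll3 replicate 1.

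The series title also names tumour-associated macrophages, so secreted factors that attract or maintain macrophages were compared. Of 19 tested, 7 were higher in the Vgll3-labelled and 6 in the Ccne1-labelled libraries (8 and 6 when adjusted over the list alone). The monocyte chemokines Ccl2 and Ccl7 rose, Ccl2 from 9.89 ± 1.06 to 90.9 ± 19.6 CPM (log2 fold change 3.20, edgeR adjusted p = 3.05e-06) and Ccl7 from 2.04 ± 0.260 to 21.9 ± 4.54 CPM (log2 fold change 3.42, edgeR adjusted p = 3.69e-06). Csf1, the main growth factor of macrophages, rose from 128 ± 13.3 to 688 ± 89.5 CPM (log2 fold change 2.43, edgeR adjusted p = 3.05e-06), and Cxcl12 from 74.7 ± 13.8 to 188 ± 40.3 CPM. Pgf, a ligand of the receptor VEGFR1, fell from 37.0 ± 17.0 to 1.58 ± 0.643 CPM (edgeR adjusted p = 0.000348), Vegfa from 297 ± 40.9 to 165 ± 30.7 CPM, and complement C3 from 57.2 ± 32.2 to 5.83 ± 7.21 CPM (edgeR adjusted p = 0.0364). The list as a set was not called (median log2 fold change 0.29, camera adjusted p = 0.517); fry, which asks only whether members moved on balance one way, gave an adjusted p of 0.0144. The C3 call ended without Ccne1 replicate 1, 2 or 3 or Vgll3 replicate 2 or 3 (edgeR adjusted p 0.0591 to 0.0996) and without a low-count filter (0.0883), and its log2 fold change moved from −3.23 to −5.06 without Vgll3 replicate 1. Macrophage markers in the same libraries summed to 73.2 ± 9.03 CPM in the Ccne1-labelled and 19.1 ± 6.36 CPM in the Vgll3-labelled libraries, of which Cd14, the 1 of 10 tested markers that was called, gave 59.4 ± 7.89 and 6.39 ± 1.85 CPM, while Csf1r was 1.08 ± 0.593 and 1.33 ± 0.936 CPM.

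Of 10 chemokines of granulocytes and lymphocytes tested, 4 rose and 1 fell in the Vgll3-labelled libraries, also when adjusted over the list alone. Cxcl10, a ligand of the chemokine receptor CXCR3, rose from 14.0 ± 5.32 to 70.0 ± 16.8 CPM and Cxcl1, a neutrophil attractant, from 152 ± 38.1 to 285 ± 99.0 CPM. Cxcl5 was 0.241 ± 0.269 and 2.26 ± 1.61 CPM (edgeR adjusted p = 0.0165), and Cxcl14 was 3.71 ± 2.48 and 0.232 ± 0.339 CPM (edgeR adjusted p = 0.0287). The list had a camera adjusted p = 0.348 and a median log2 fold change of 0.60. The Cxcl5 call ended without Vgll3 replicate 1 (log2 fold change 2.45, edgeR adjusted p = 0.0612), where 2 chemokines rose, while its log2 fold change moved from 3.23 to 4.33 without Ccne1 replicate 3. The Cxcl14 call ended without Ccne1 replicate 1, 2 or 3 or Vgll3 replicate 2 or 3 (edgeR adjusted p 0.0514 to 0.0894), without a low-count filter (0.0959) and with limma-voom (0.0989), and its log2 fold change moved from −3.82 to −6.56 without Vgll3 replicate 1.

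Target genes of the YAP and TAZ cofactors with TEAD were on balance lower in the Vgll3-labelled libraries. Of 22 tested, 10 fell and 2 rose (10 and 3 when adjusted over the list alone). Ccn2 fell from 84.9 ± 26.7 to 9.66 ± 2.24 CPM (log2 fold change −3.13, edgeR adjusted p = 0.000258), Nt5e (the ecto-5′-nucleotidase CD73) from 263 ± 26.8 to 24.96 ± 5.33 CPM, and Ankrd1 from 218 ± 21.4 to 75.7 ± 3.58 CPM. Ccn1, another target, was 1605 ± 396 and 1138 ± 217 CPM and was not called (edgeR adjusted p = 0.0727). Nuak2 rose from 3.16 ± 0.284 to 8.44 ± 0.308 CPM and Fjx1 from 6.32 ± 2.04 to 10.5 ± 1.10 CPM (edgeR adjusted p = 0.0293). The median log2 fold change was −0.30 and the camera adjusted p = 0.0146, with adjusted p = 0.596 with an estimated correlation. The Fjx1 call ended without Ccne1 replicate 2 or 4 or Vgll3 replicate 2 or 3 (edgeR adjusted p 0.0544 to 0.0764). Without Ccne1 replicate 2 or Vgll3 replicate 2, 1 target rose.

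Cell cycle genes were higher in the Vgll3-labelled libraries. Of 28 genes of the G1/S transition and DNA replication, 25 rose and 0 fell (27 and 0 when adjusted over the list alone), and of 24 genes of G2/M and mitosis 22 rose and 0 fell, also when adjusted over the list alone. E2f2, an S-phase transcription factor, rose from 2.44 ± 0.208 to 9.43 ± 1.12 CPM (log2 fold change 1.95, edgeR adjusted p = 2.31e-05). Ccne2, the paralog of Ccne1, rose from 5.27 ± 0.418 to 16.4 ± 0.823 CPM (log2 fold change 1.64, edgeR adjusted p = 1.04e-05). E2f2 and Ccne2 both lie on chromosome 4, where the median log2 fold change relative to all genes was 0.46. The mitotic kinesin Kif20a rose from 32.4 ± 9.30 to 88.0 ± 8.46 CPM, and Mki67, the gene of the proliferation marker Ki-67, from 158 ± 30.4 to 329 ± 49.1 CPM. The median log2 fold changes were 0.65 for G1/S (camera adjusted p = 2.57e-07) and 0.92 for G2/M (camera adjusted p = 1.76e-07). Both had adjusted p = 0.596 with an estimated correlation.

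Of 17 target genes of p53 tested, 4 were higher in the Vgll3-labelled and 7 in the Ccne1-labelled libraries, also when adjusted over the list alone. Btg2, an antiproliferative gene, rose from 10.6 ± 1.07 to 39.9 ± 8.05 CPM (edgeR adjusted p = 1.67e-05), and Pmaip1, which encodes the apoptosis factor NOXA, fell from 61.8 ± 3.11 to 25.9 ± 9.84 CPM (edgeR adjusted p = 0.00263). Cdkn1a, the gene of p21, was 63.4 ± 18.6 and 37.0 ± 13.5 CPM (edgeR adjusted p = 0.0699). The set was not called (median log2 fold change −0.27, camera adjusted p = 0.539).

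Interferon-stimulated genes were higher in the Vgll3-labelled libraries. Of 27 tested, 21 rose and 0 fell (23 and 0 when adjusted over the list alone), with a median log2 fold change of 1.52, and a camera adjusted p = 9.41e-07 (adjusted p = 0.600 with an estimated correlation). Oas3, a sensor of double-stranded RNA, rose from 0.467 ± 0.241 to 4.46 ± 3.51 CPM (log2 fold change 3.22, edgeR adjusted p = 0.00257). Ifih1, the RNA sensor MDA5, rose from 5.37 ± 2.06 to 31.4 ± 3.22 CPM, and Rsad2 (viperin) from 5.55 ± 2.92 to 30.9 ± 7.99 CPM. Near-identical copies such as Ifit3 and Ifit3b can share reads, so their separate values are uncertain. Without Vgll3 replicate 3 the log2 fold change of Oas3 was 2.38 and 1 member fell.

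Of 14 genes of MHC class I presentation, 7 rose and 1 fell in the Vgll3-labelled libraries, also when adjusted over the list alone. The immunoproteasome gene Psmb9 was 7.34 ± 3.01 and 17.7 ± 7.48 CPM (edgeR adjusted p = 0.0294), and the peptide transporter Tap1 rose from 49.9 ± 12.1 to 94.1 ± 15.7 CPM. H2-T23, the mouse Qa-1 molecule, fell from 35.4 ± 5.26 to 18.7 ± 5.64 CPM (edgeR adjusted p = 0.00596). B2m was 1447 ± 284 and 1381 ± 79.9 CPM and was not called (edgeR adjusted p = 0.721). The set was not called (median log2 fold change 0.31, camera adjusted p = 0.135), and the Psmb9 call ended without Ccne1 replicate 1 or 4 or Vgll3 replicate 3 (edgeR adjusted p 0.0568 to 0.0815) and without a low-count filter (0.0826). Members that fell numbered 2 without Ccne1 replicate 1 and 3 without Vgll3 replicate 3.

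Genes of hypoxia and glycolysis were more often lower than higher in the Vgll3-labelled libraries. Of 23 tested, 13 fell and 1 rose, also when adjusted over the list alone. Adm, the gene of adrenomedullin and a hypoxia target, fell from 143 ± 36.8 to 22.6 ± 15.97 CPM (log2 fold change −2.65, edgeR adjusted p = 0.00645). The glucose transporter Slc2a1 fell from 1101 ± 390 to 380 ± 183 CPM and Bnip3 from 416 ± 85.7 to 117 ± 58.0 CPM. Car9, also a hypoxia target, was 62.0 ± 15.7 and 65.3 ± 48.0 CPM (edgeR adjusted p = 0.904). Eno1 was the gene that rose, from 1623 ± 151 to 2112 ± 359 CPM (edgeR adjusted p = 0.0299). Its log2 fold change of 0.38 lay under the median of 0.46, relative to all genes, on its chromosome 4. The median log2 fold change was −0.50 and the camera adjusted p = 0.00515, with adjusted p = 0.714 with an estimated correlation; fry did not call the list (adjusted p = 0.0807). The Eno1 call ended without any 1 of Ccne1 replicates 1, 3 and 4 and Vgll3 replicates 1 and 2 (edgeR adjusted p 0.0546 to 0.113), and without Vgll3 replicate 1 the log2 fold change of Adm was −3.39.

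Integrins were also lower in the Vgll3-labelled libraries, with 10 of 16 falling and 1 rising (10 and 2 when adjusted over the list alone). Itgb3, which with Itgav forms a receptor that binds periostin and other matrix proteins, fell from 82.0 ± 10.03 to 5.44 ± 4.43 CPM (log2 fold change −3.94, edgeR adjusted p = 0.00149). Itgav fell from 468 ± 17.5 to 338 ± 51.1 CPM. Itga4 rose from 0.530 ± 0.357 to 10.6 ± 2.14 CPM (log2 fold change 4.33, edgeR adjusted p = 0.000119). The median log2 fold change was −0.57 and the camera adjusted p = 0.0135, with adjusted p = 0.496 with an estimated correlation. Without Vgll3 replicate 3 the log2 fold change of Itgb3 was −4.86, and without Vgll3 replicate 1, 2 integrins rose.

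Matrix proteases and their inhibitors split almost evenly, with 10 of 22 higher in the Vgll3-labelled and 9 in the Ccne1-labelled libraries (10 and 10 when adjusted over the list alone). Among those higher in the Ccne1-labelled libraries, Mmp3 was 249 ± 138 against 4.30 ± 3.83 CPM (log2 fold change −5.79, edgeR adjusted p = 0.00222), Mmp10 3896 ± 1472 against 196 ± 262 CPM and Mmp13 2199 ± 933 against 55.2 ± 68.1 CPM. Mmp23 rose from 1.06 ± 0.475 to 6.19 ± 0.936 CPM (edgeR adjusted p = 0.000416), and the procollagen protease Adamts2 from 44.1 ± 5.99 to 250 ± 78.3 CPM. The median log2 fold change was 0.05 while the mean was −0.63, and the set test pointed down without a call (camera adjusted p = 0.735). Without Vgll3 replicate 1 the log2 fold change of Mmp3 was −6.90.

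Genes of mesenchymal and stromal identity also went both ways, with 7 of 22 higher in the Vgll3-labelled and 9 in the Ccne1-labelled libraries (8 and 9 when adjusted over the list alone). Fap, a protease of activated fibroblasts, rose from 0.663 ± 0.3998 to 19.4 ± 9.95 CPM (log2 fold change 4.89, edgeR adjusted p = 0.000425). Cdh11 rose from 29.9 ± 6.27 to 232 ± 22.8 CPM. The PDGF receptors moved apart: Pdgfrb rose from 188 ± 25.4 to 825 ± 275 CPM and Pdgfra fell from 919 ± 60.1 to 226 ± 46.1 CPM. Vim (vimentin), the gene with the most counts in each Ccne1-labelled library, fell from 13973 ± 1413 to 4375 ± 238 CPM. Dpt was 12.8 ± 6.84 and 1.83 ± 1.20 CPM (edgeR adjusted p = 0.0174). The set was not called (median log2 fold change −0.31, camera adjusted p = 0.726), and the Dpt call ended without Vgll3 replicate 3 (edgeR adjusted p = 0.0672), without a low-count filter (0.0598) and with limma-voom (0.0874). The log2 fold change of Dpt moved from −2.76 to −3.37 without Vgll3 replicate 1.

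Among lineage genes, 2 of 8 skeletogenic genes rose and 6 fell, also when adjusted over the list alone (median log2 fold change −1.40, camera adjusted p = 0.139). Acan, the cartilage proteoglycan aggrecan, fell from 91.8 ± 19.8 to 3.08 ± 3.54 CPM (edgeR adjusted p = 0.0025), Sox9 fell from 335 ± 33.9 to 151 ± 28.1 CPM, and Msx2 rose from 2.05 ± 0.420 to 4.61 ± 0.914 CPM. Of 11 adipogenic genes, 3 rose and 5 fell, also when adjusted over the list alone (median log2 fold change −0.63, camera adjusted p = 0.683). Cebpb fell from 618 ± 116 to 146 ± 37.0 CPM, Acsl1 rose from 18.0 ± 1.01 to 30.4 ± 0.643 CPM, and Cd36 was 0.483 ± 0.364 and 0.0967 ± 0.0477 CPM (edgeR adjusted p = 0.0474). Of 8 myogenic genes, 2 rose and 1 fell (1 and 0 when adjusted over the list alone). Cdh15 had the large rise given above, Des (desmin) was 0.776 ± 0.196 and 1.58 ± 0.298 CPM, and Tnnc1 was 1.57 ± 0.207 and 0.694 ± 0.353 CPM (edgeR adjusted p = 0.045). The myogenic median log2 fold change was −0.20, the mean 1.10 and the set test pointed up (camera adjusted p = 0.886). The Cd36 call ended without any 1 Vgll3-labelled library (edgeR adjusted p 0.0530 to 0.137), with total library sizes (0.0528), without a low-count filter (0.0561) and with limma-voom (0.113), and the Tnnc1 call on leaving out any library but Vgll3 replicate 1 (0.0580 to 0.0912) and without a low-count filter (0.0628). The log2 fold change of Acan moved from −4.92 to −6.39 without Vgll3 replicate 3 and to −5.57 with limma-voom. Adipogenic genes that fell numbered 3 without Ccne1 replicate 1, 2 or 3 or Vgll3 replicate 1 or 2, skeletogenic genes that rose numbered 1 without Vgll3 replicate 2, and myogenic genes that rose numbered 1 without Ccne1 replicate 1, 3 or 4 or Vgll3 replicate 1 or 2. Myogenic genes that fell numbered 0 without any 1 Ccne1-labelled library or Vgll3 replicate 2, and 2 without Vgll3 replicate 3. The myogenic set test pointed down without Vgll3 replicate 3 (camera adjusted p = 0.745).

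Of 21 genes of the TGF-beta pathway, 6 rose and 7 fell, also when adjusted over the list alone (median log2 fold change −0.18, camera adjusted p = 0.594). Tgfbr3 rose from 39.995 ± 7.86 to 72.6 ± 14.9 CPM and Ltbp1, which stores latent TGF-beta in the matrix, fell from 894 ± 93.1 to 258 ± 50.9 CPM (edgeR adjusted p = 2.75e-05). Of 12 contractile genes, 6 rose and 2 fell, also when adjusted over the list alone (median log2 fold change 0.37, camera adjusted p = 0.0955). Smooth muscle actin genes rose, Actg2 from 55.2 ± 7.02 to 176 ± 7.21 CPM (edgeR adjusted p = 7.52e-06) and Acta2 from 74.7 ± 35.1 to 226 ± 59.9 CPM, while skeletal actin Acta1 fell from 3.30 ± 0.726 to 0.204 ± 0.194 CPM. Without Vgll3 replicate 2, 3 TGF-beta genes and 3 contractile genes rose, and the log2 fold change of Acta1 moved from −3.91 to −4.88 without Vgll3 replicate 1 and to −4.68 with limma-voom. With the preset correlation, camera called 7 of the 19 pathway lists, and with an estimated correlation it called 0, with 1 list at an unadjusted p under 0.05. The run with an estimated correlation has few degrees of freedom, so its missing calls decide little. Fry called collagens, macrophage attractants, YAP/TAZ-TEAD targets and G1/S genes among the primary lists and 8 secondary lists. Of the 7 lists that camera called, it did not call hypoxia and glycolysis genes.

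**Figure D2:**
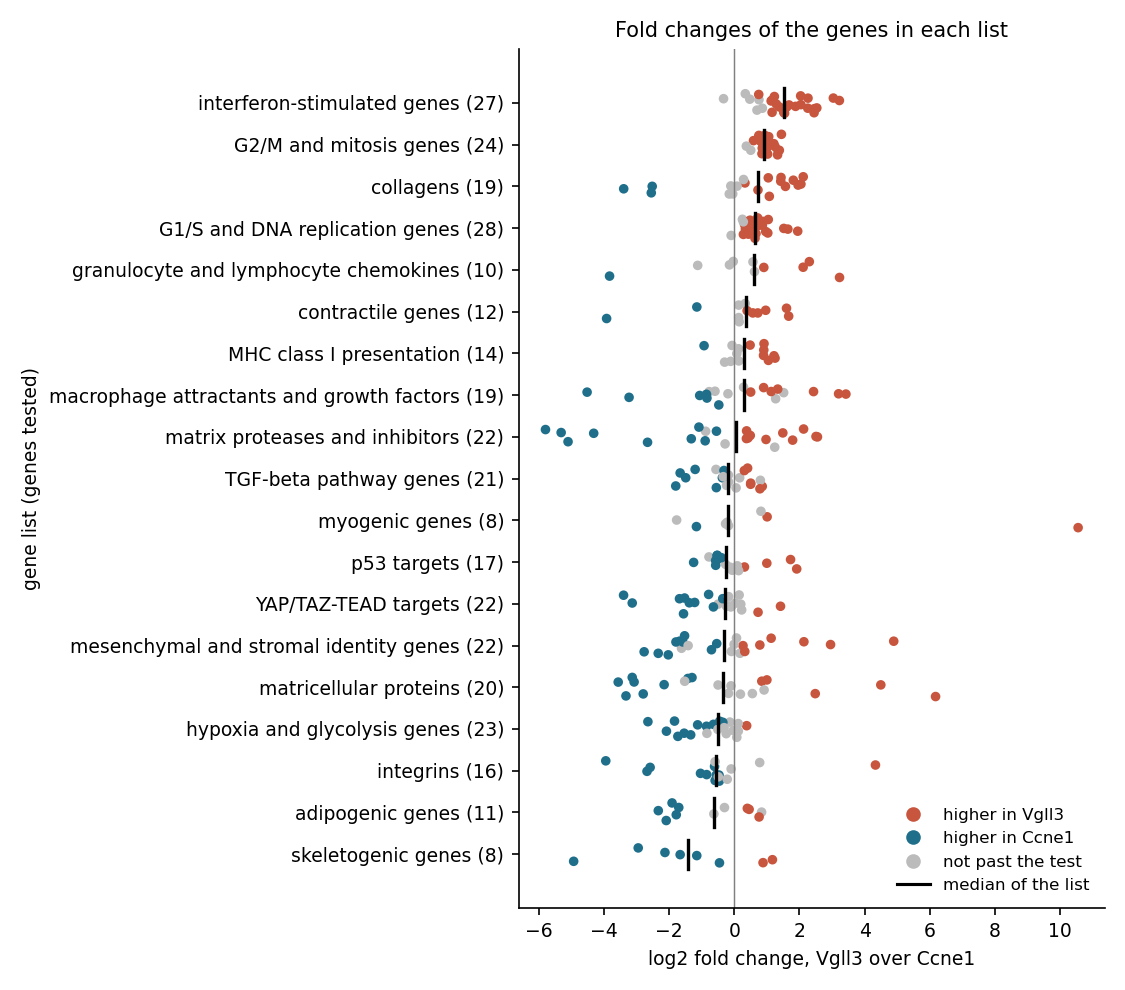
Log2 fold changes (Vgll3-labelled over Ccne1-labelled) of the members of the 19 pathway lists; each point is a gene, and the bar marks the list's median. Interferon-stimulated, G2/M and G1/S genes lie mostly above 0 (medians 1.52, 0.92 and 0.65), and integrins and hypoxia genes mostly below (medians −0.57 and −0.50).

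Markers of host cells that could pass the RFP sort were low for most cell types. The 18 macrophage markers summed to 73.2 ± 9.03 CPM in the Ccne1-labelled and 19.1 ± 6.36 CPM in the Vgll3-labelled libraries (exact permutation p = 0.0286, adjusted 0.0857). This is the smallest p the splits allow, and too few lists reached it for any adjusted p under 0.05. Cd14, the marker with the highest mean, was 59.4 ± 7.89 and 6.39 ± 1.85 CPM (edgeR adjusted p = 1.63e-05), and it was the 1 of 10 tested members that was called; Csf1r was 1.08 ± 0.593 and 1.33 ± 0.936 CPM. Endothelial markers summed to 91.1 ± 42.4 and 118 ± 110 CPM, with 0 of 11 called by edgeR and 0 at an unadjusted p under 0.05. Vgll3 replicate 3 alone, at 244 CPM, put the Vgll3-labelled mean above the Ccne1-labelled mean, since replicates 1 and 2 had 37.2 and 73.8 CPM. Pecam1 was 41.7 ± 23.4 and 79.7 ± 90.8 CPM, with a log2 fold change of 0.94 that turned to −0.60 without Vgll3 replicate 3. Pericyte markers summed to 521 ± 42.5 and 159 ± 13.3 CPM (exact permutation p = 0.0286, adjusted 0.0857), of which Cspg4 (NG2) gave 514 ± 42.4 and 140 ± 10.2 CPM (edgeR adjusted p = 3.86e-06). Rgs5 and Notch3, also pericyte markers, rose from 0.543 ± 0.328 to 5.95 ± 1.89 CPM and from 4.00 ± 1.67 to 11.7 ± 5.24 CPM.

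The remaining marker lists had small sums, of which those of erythroid and mature muscle markers did not overlap between the groups (exact permutation p = 0.0286, adjusted 0.0857, for each). Erythroid and platelet markers were 8.84 ± 1.95 and 1.77 ± 1.12 CPM, with 3 of 4 tested higher in the Ccne1-labelled libraries, among them Hba-a1 (6.58 ± 2.64 and 0.755 ± 0.491 CPM, edgeR adjusted p = 0.00241), which shares reads with its copy Hba-a2. Dendritic cell and MHC class II markers were 5.43 ± 3.96 and 9.36 ± 3.56 CPM with Cd74 at 2.17 ± 1.503 and 4.15 ± 2.18 CPM, and T and NK cell markers 1.51 ± 0.481 and 2.29 ± 0.805 CPM with Lck at 0.685 ± 0.126 and 1.01 ± 0.0871 CPM. B cell markers were 2.73 ± 1.62 and 4.24 ± 1.52 CPM with Cd79a at 0.705 ± 0.338 and 1.78 ± 1.68 CPM, and neutrophil markers 0.962 ± 0.142 and 1.25 ± 0.255 CPM with Cxcr2 at 0.675 ± 0.179 and 1.06 ± 0.372 CPM. Cd79a was not called with all libraries (edgeR adjusted p = 0.111) and was called without Vgll3 replicate 1 (0.0404), while its log2 fold change moved from 1.33 to 0.21 without Vgll3 replicate 3. Epithelial markers were 4.44 ± 1.27 and 3.04 ± 0.821 CPM, with 1 of 2 tested higher in the Ccne1-labelled libraries and Krt10 at 1.56 ± 0.530 and 2.46 ± 0.471 CPM. Mature muscle markers were 5.18 ± 0.602 and 2.58 ± 0.388 CPM, with 1 of 4 tested higher and 1 lower in the Vgll3-labelled libraries, and adipocyte markers were 0.170 ± 0.112 and 0.128 ± 0.0651 CPM with 0 tested. Camera called 0 of the marker lists, also at an unadjusted p under 0.05.

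**Figure D3:**
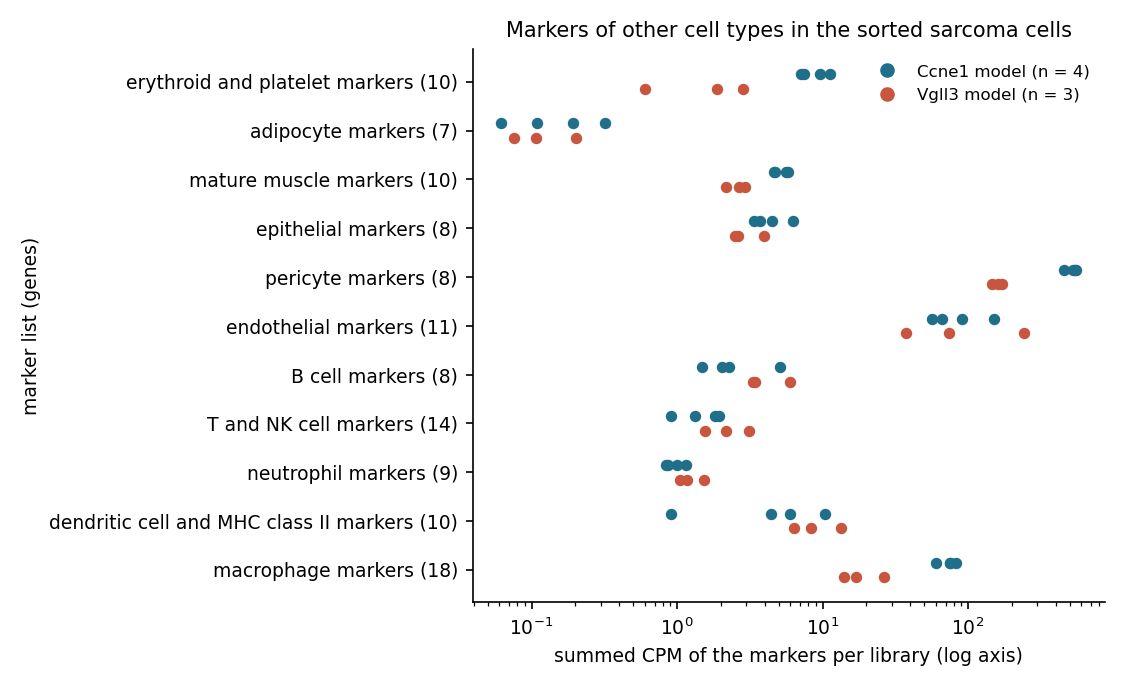
Summed CPM of each host marker list in each library, on a log axis; points are libraries, coloured by group. Macrophage sums lie between 60.6 and 82.2 CPM in the Ccne1-labelled and between 14.1 and 26.2 CPM in the Vgll3-labelled libraries.

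Signs of RNA handling were mixed. Of 15 immediate early and heat shock genes, 3 were higher in the Vgll3-labelled and 4 in the Ccne1-labelled libraries (3 and 3 when adjusted over the list alone), with a median log2 fold change of 0.06, a mean of −0.07 and a camera adjusted p = 0.864. Jun was 3346 ± 398 and 5180 ± 920 CPM (edgeR adjusted p = 0.00461), Egr1 rose from 183 ± 12.3 to 1376 ± 53.2 CPM and Ier3 fell from 841 ± 150 to 152 ± 67.7 CPM. The share of counts in ribosomal protein genes was 4.24% ± 0.210 and 5.31% ± 0.532, and the 10 genes with the most counts took 6.48% ± 0.354 and 9.58% ± 0.477 (exact permutation p = 0.0286 for each). Mitochondrial transcripts took 2.01% ± 0.138 and 2.06% ± 0.129 (exact permutation p = 0.486). Genes of olfactory, vomeronasal and trace amine receptors, which sarcoma cells are not known to use, summed to 1257 CPM in Vgll3 replicate 3 and to between 247 and 361 CPM in the other libraries.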

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

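All tests on the Ccne1 level in this part were chosen after its values had been seen. Vgll3 in Ccne1 replicate 1 was 37.9 CPM, while the other 3 Ccne1-labelled libraries held 54.3 to 56.2 CPM; the gap is larger than Dixon's limit for 4 samples. It was 1 of 83 values screened, and chance sets apart about 1 in 20 groups.

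The pattern a reader would most want to follow is that Ccne1 was not higher in the libraries labelled for its overexpression. An exchange of the group labels is argued against by Vgll3, whose log2 fold change of 2.31 (SE 0.15) has the sign that the labels give. Too few counts to see a 2-fold difference are argued against by the lower 95% bound of the Ccne1 log2 fold change, −0.58, which leaves at most a 1.49-fold higher level in the Ccne1-labelled libraries. A vector transcript that was not counted under the mouse gene stays open: the table has 0 entries other than mouse Ensembl genes, so it cannot be told apart from an insert lost or silenced during passage. The series has no normal or parental cells, so whether Ccne1 was low or raised in both groups cannot be told either. The biological explanation, a tumour line that no longer carries a high Ccne1 level, was not tested.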

How the results depend on the processing

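The reading of the split counts was written down after they had been seen. Of 66 named genes, 65 kept their direction and 49 their direction and call under every alternative run on single genes, the block included. Calls that changed only under the block are not marked beside their genes above. Of 983 values, 910 kept direction and call. The number of called genes was 6649 without a low-count filter, 6910 with at least 1 CPM in 3 libraries, 7091 with total library sizes, 7157 with DESeq2 size factors, 7224 with limma-voom and 7446 with DESeq2. These shared 89.4% to 98.7% of the 7133 calls, with 0 shared calls of opposite sign. Against a 1.5-fold threshold (glmTreat), which by construction asks for larger changes, 2288 genes were called, 1171 higher in the Vgll3-labelled and 1117 in the Ccne1-labelled libraries. Leaving out 1 library gave 6023 to 7334 genes (2894 to 3577 and 3129 to 3757). The replicate numbers gave no sign of a positive pairing: deviations of same-numbered libraries correlated at −0.151, −0.167 and −0.103. These lay below all other pairs between the groups (−0.0356 to 0.155), and why was not tested. The replicate block called 4845 genes, 2293 of them higher in the Vgll3-labelled libraries, against 6288 for the same 6 libraries without it; camera adjusted p was 0.0570 for collagens and 0.926 for myogenic genes, whose direction reversed, and the cause was not tested. With an estimated correlation, camera called 0 primary and 0 secondary lists (1 at an unadjusted p under 0.05). Collagens, YAP/TAZ-TEAD targets and G1/S genes each had camera adjusted p = 0.596. Their estimated correlations were 0.17, 0.041 and 0.58, against the preset 0.01, and a higher correlation raises camera's p. Integrins lost their call too, at an estimated correlation of −0.061, so a raised correlation was not the cause for every list. When camera estimates the correlation, it also takes its degrees of freedom from the 7 libraries and not from the genes. That raises its p at any correlation. Fry gave 0.0144 for macrophage attractants and 0.0807 for hypoxia and glycolysis genes, and called 8 secondary lists; it does not compare a list with other genes. The log2 fold change of Pecam1 ran from −0.60 (without Vgll3 replicate 3) to 1.4 over the libraries left out, and the adjusted p of the myogenic list from 0.745 to 0.990, with its direction reversed without Vgll3 replicate 3. Of the 35 splits, 1 (the real one) gave as many as 7133 genes and the highest other gave 1. That is an exact permutation p of 0.0286, the smallest these splits allow. Each other split mixes the 2 groups on at least 1 side, which widens the spread there and keeps gene calls few. For lists called by camera, 6 of 35 splits gave as many as the real 7, and the highest other gave 8. The number of lists called thus does not set the real split apart. Depth limits genes under about 0.1 CPM, near the floor of 3 counts.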

Other observations

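The tests on Vgll3 replicate 3 and on the chromosomes, and the genes and families named in this part, were chosen after the values had been seen. The TEAD transcription factors, which both Vgll3 and YAP bind, differed in both directions. Tead4 was 15.7 ± 2.70 CPM in the Ccne1-labelled and 1.39 ± 0.798 CPM in the Vgll3-labelled libraries (log2 fold change −3.52, SE 0.35, edgeR adjusted p = 0.000123), and Tead3 was 28.8 ± 1.26 and 19.3 ± 2.63 CPM (edgeR adjusted p = 0.0014). Tead1 rose from 277 ± 10.1 to 429 ± 20.7 CPM (edgeR adjusted p = 0.000108) and Tead2 from 65.1 ± 7.09 to 138 ± 9.45 CPM (edgeR adjusted p = 3.74e-05). Yap1 was 179 ± 13.6 and 188 ± 21.3 CPM (edgeR adjusted p = 0.601), and Wwtr1, the gene of TAZ, fell from 434 ± 18.0 to 367 ± 20.6 CPM (edgeR adjusted p = 0.0208).

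Among 224 gene families formed by symbol, camera called 3, each with adjusted p = 0.959 with an estimated correlation. With few degrees of freedom and 224 families, the run with an estimated correlation could hardly call any. The Ifi family of interferon-inducible genes had 10 of 15 members higher in the Vgll3-labelled libraries (median log2 fold change 1.77, camera adjusted p = 0.0256). Members outside the interferon list rose too, such as Ifi204 and Ifi203, cytosolic DNA sensors, with log2 fold changes of 2.91 and 3.07. The other families were the olfactory receptors, with 26 of 111 higher and 3 lower (camera adjusted p = 0.0156), and the vomeronasal receptors, with 21 of 56 higher and 0 lower (0.0256). Over all receptor genes 47 were higher and 3 lower of 166 tested, and without Vgll3 replicate 3, 17 and 3 of 173.

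Vgll3 replicate 3 stood apart from the other libraries of its group. Its receptor genes summed to 3.48 times the next highest library (1257 against 361 CPM), consistent with background reads such as genomic DNA. It stood apart among well expressed genes too: over 8831 genes with a mean of at least 10 CPM, its highest r with its group was 0.969. The other same-group pairs had 0.982 to 0.993. How many background reads fell in those genes was not measured, so this r does not decide their part there. Endothelial markers also summed to 244 CPM in Vgll3 replicate 3, against 37.2 and 73.8 CPM in Vgll3 replicates 1 and 2. Ccne1 replicate 1 had 151 CPM. Whether host cells that passed the sort set Vgll3 replicate 3 apart was not tested. A fixed share of RNA of the Ccne1 model mixed into it could not be excluded: of 43 genes at least 16-fold higher in every Ccne1-labelled library than in Vgll3 replicates 1 and 2, 3 (6.98%) had an upper bound under the third part of the level that the median implied share of 10.6% needs. The rule that reads 6.98% as undecided was set after this value was known. A looser count, also added after that result had been seen, found 11 (25.6%) under the level itself, with implied shares from −1.64% to 105%. This looser count allows for counting error alone and not for variation in the mixed RNA.

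Fold changes were shifted over whole chromosomes: over 12102 genes, the median log2 fold change relative to all genes was 0.46 on chromosome 4, 0.39 on 6, 0.31 on 18 and 0.19 on 12, and −0.28 on 11 and −0.33 on 17; on chromosome 4, 60.3% of genes were called higher in the Vgll3-labelled libraries, and on 17, 53.9% were called lower. A chance order of clustered genes is argued against, since the SD of chromosome medians was 0.2057 and the highest of 10000 rotations of the fold changes along the genome 0.2055, with a median of 0.167 (permutation p = 0.0001, the smallest they can give). GC content and transcript length are argued against as the whole cause, as 97.0% of that SD was left after regression on both, but the regression moved chromosome 12 from 0.19 to 0.12 and X from −0.18 to −0.27, so that 12 left the 6 most shifted. A hypothesis is that the lines may differ in copies of whole chromosomes: 97.1% of windows of 50 genes (67 of 69) on the 6 chromosomes most shifted before that regression had the sign of their chromosome, against a 95th percentile of 94.6% in rotations; copy number was not measured.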
